A study of Mus musculus with 24 samples.

How the data were processed

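Total RNA from primary cultures of mouse fetal cortex and midbrain was hybridised as biotin-labelled cDNA to 24 whole-transcript mouse gene arrays, 1 sample per array, per the labels' protocols. The authors deposited 1 table of log2 values, described in the labels as normalized, with 28856 probe sets and 24 arrays. The log2 scale of the deposited values was read from their range and array medians. The method of background correction and normalization is not given in the sources used here, so a shift shared by all genes of an array would not be visible, and fold changes are relative to the typical gene. The labels give array run 1 for the 6 midbrain 13 d arrays and run 2 for the other 18. No depth exists for arrays, and signal over background cannot be read from normalized values.

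Groups, comparisons, alternatives, 25 gene lists and the rule for naming genes were fixed before the data were examined. The probe table gave at least 1 gene symbol for 23410 probe sets, which were tested. Of these, 21789 had 1 symbol, covering 19938 genes, and 1621 had several. A further 5446 probe sets are unnamed here. Entrez numbers of 21698 single-symbol probe sets were found in the gene table of assembly GRCm38.p6, and 0 symbols changed. No coordinates are given because the files name no build.

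Limma 3.58.1 in R 4.3.3 fitted the 8 group means to all 24 arrays with 16 residual degrees of freedom, followed by eBayes with default settings. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The 10 comparisons were the oxygen response in each of 4 region and time groups, 4 differences between such responses, midbrain against cortex at labelled 48 h, and labelled 13 d against 48 h in cortex, the last pair at 21% O2. Midbrain 13 d against midbrain 48 h or cortex 13 d at 1 oxygen level was not tested, since array run and group cannot be told apart there.

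Gene lists were tested with camera (preset inter-gene correlation of 0.01, 1 probe set per gene, the one with the highest mean), adjusted over the 25 lists of a comparison. Of the lists called with the preset correlation, those that held with an estimated one numbered 0 of 7 in midbrain 48 h, 0 of 10 in midbrain 13 d, 1 of 13 in cortex 48 h, 2 of 11 in cortex 13 d, 3 of 14 between regions and 3 of 15 between the cortex times. In the 4 differences of responses 0 held, of 9, 9, 13 and 7. Members of a list were counted past the threshold over all probe sets and adjusted over the list alone. Lists share some members, for example collagen genes of the matrix and fibroblast lists.

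Genes named in the text followed a fixed rule. It took the 8 largest rises and 8 largest falls past the threshold with no overlap between the groups (6 and 6 for differences, without that condition), the 2 members of each list with the smallest p, and a fixed panel of hypoxia and cell type genes. Clone-type symbols were passed over, as were Xist and Y-linked genes. Separation of the groups, which chance gives in 10% of probe sets for 3 arrays against 3, was not used for counts.

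Same-numbered arrays at 3% and 21% O2 deviated together in midbrain, with correlations of 0.12, 0.22 and 0.24 at 48 h and 0.12, 0.42 and 0.31 at 13 d. Each lay above the preset limit of 0.1, so the numbers were taken to pair the midbrain arrays, although replicate 1 at 13 d correlated more with an array of another number (0.16). This pairing comes from the data, since the labels do not say what a number shares. It did not hold in cortex. The main fit, which gave the midbrain values below, did not use the pairing. With the replicate block, 224 of its 279 calls in midbrain 48 h and 5322 of its 5584 calls in midbrain 13 d were kept. Replicates were compared before averaging, and the closest pair differed with an SD of 0.0904, so none was treated as a duplicate.

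Alternatives were all 28856 probe sets, the 11705 brighter probe sets, quantile normalization, median centring, a variance trend with robust moderation, fits of the compared arrays alone, array weights, the replicate block and leaving out each array. The default array weight estimate stopped before convergence, and the gene-by-gene estimator was added after its counts had been seen. Fits of the 12 midbrain arrays, crossed cortex times and the omission of the number 1 arrays of cortex 48 h were also added after the data were seen. The model was tested on simulated arrays with 200 changed probe sets among 23410. For the midbrain 48 h comparison it recovered 94.0% of changes of 0.5, 100.0% of 1, 100.0% of 2 and 96% of -1 on the log2 scale, with 14 false calls. With the replicate block these shares were 88%, 100%, 100% and 94%, with 9 false calls. For simulated differences of responses it recovered less of the small changes, with 68% of changes of 0.5 and 92% of -1 for the midbrain time difference, and 66% and 90% for the regions at 48 h. The simulated noise was independent between arrays and probe sets, with the same SD of a probe set in all arrays. Uneven arrays, pairs and unequal spread of the groups were thus not covered. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.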

Results

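RNA from primary neural stem cell cultures of the mouse fetal cortex and midbrain (mesencephalon), prepared at embryonic day 14 from C57Bl/6 mice, was measured on 24 whole-transcript arrays. The cultures had been kept in expansion medium, which favours dividing progenitors, for 48 h or 13 d, in 3% O2 or in 21% O2, the level of room air. Region, culture time and oxygen gave 8 groups of 3 arrays. The log2 values spanned 4.65 to 14.49, array medians lay between 7.35 and 7.42, and Pearson correlations between arrays of a group lay between 0.986 and 0.999. The number of arrays limits the precision. The labels do not say that arrays of a group came from separate cultures or animals, so the p-values measure only the spread between these arrays, which may be technical. Fold changes below are log2 values with their standard error and n = 3 arrays per group, and a gene is said to have risen or fallen only where limma's adjusted p was under 0.05 among 23410 probe sets.

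Across all tested probe sets, the cortex groups were closer to the midbrain groups of the other labelled time than to those of the same. This held for all 12 cortex arrays by Pearson correlation. The mean of 24 neuron genes was 11.30 ± 0.05 (log2, SD, n = 3) in midbrain 48 h at 21% O2 and 11.03 ± 0.05 in the cortex arrays labelled 13 d. It was 8.22 ± 0.06 in midbrain 13 d and 8.88 ± 0.14 in the cortex arrays labelled 48 h. The oligodendrocyte lineage list ran the other way, at 7.84 ± 0.14 and 7.84 ± 0.03 in the first pair and at 9.39 ± 0.06 and 9.79 ± 0.74 in the second. Not all lists paired the groups in this way. The mean of 37 cell cycle genes was 9.00 ± 0.26 in midbrain 48 h and 10.29 ± 0.04 in cortex labelled 13 d. It was 10.08 ± 0.05 in midbrain 13 d and 10.51 ± 0.23 in cortex labelled 48 h, all at 21% O2. Culture times of the cortex arrays are therefore given below as labelled. The midbrain 13 d arrays formed array run 1 and the other 18 arrays run 2, so levels of midbrain 13 d against other groups cross the run, which cannot be told apart from the group.

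**Figure D1:**
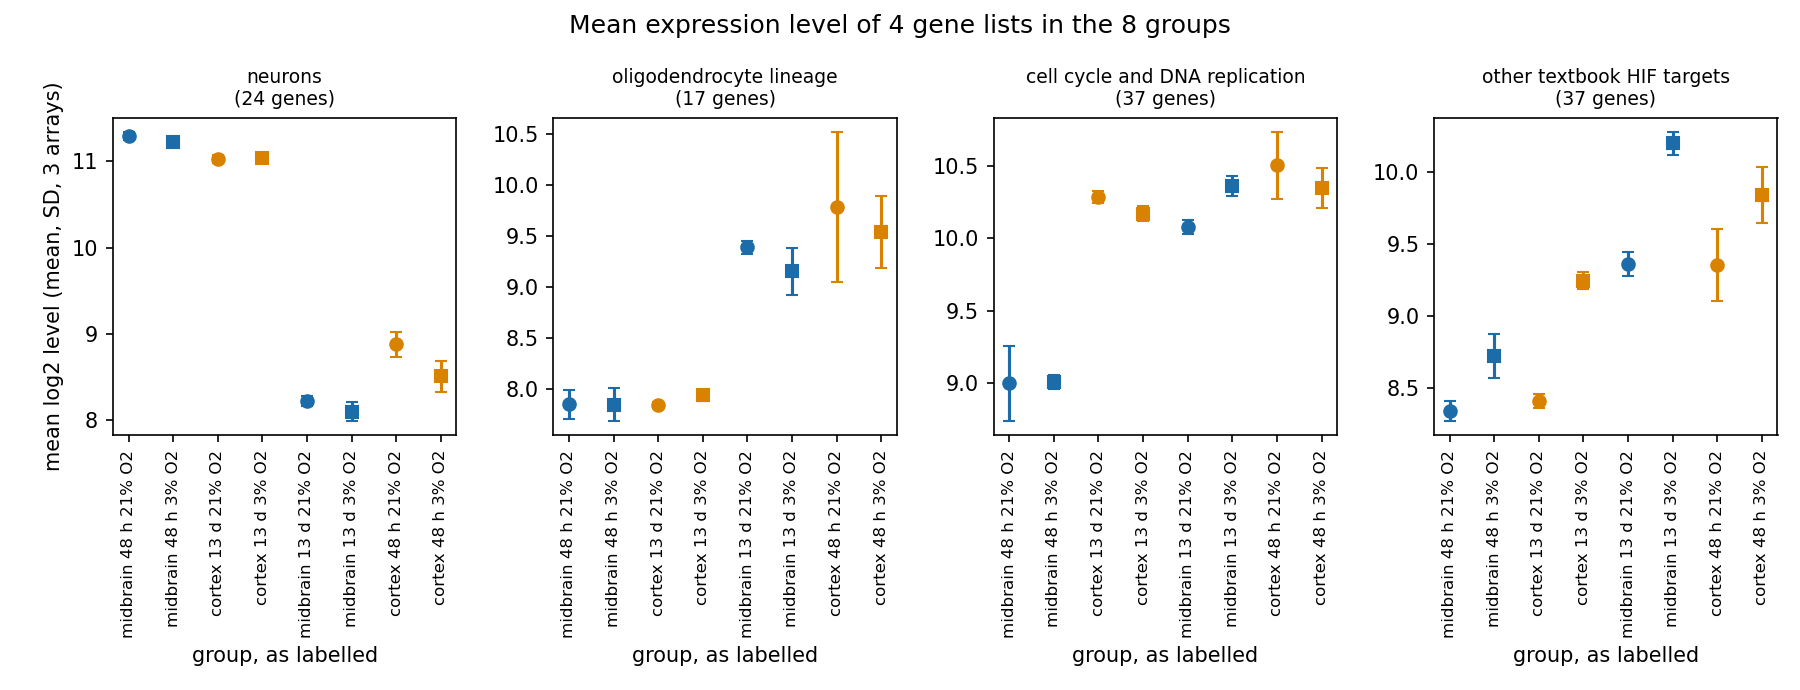
Mean log2 level of 4 gene lists (y axis) in the 8 groups as labelled (x axis), midbrain in blue and cortex in orange, circles for 21% O2 and squares for 3% O2, with the mean and SD of 3 arrays. Midbrain 48 h and cortex labelled 13 d lie above 11 for neuron genes, and midbrain 13 d and cortex labelled 48 h lie below 9.

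The first question was how low oxygen changed expression in short-term midbrain cultures. The 8 largest rises named by the rule held genes of glucose use beside others, such as the mitophagy receptor gene Bnip3 (1.52 ± 0.30). Slc16a3, a lactate exporter, rose by 2.50 ± 0.30 (adjusted p = 0.000252, a 5.64-fold change). Pdk1, a kinase that restrains the use of pyruvate by mitochondria, rose by 1.57 ± 0.23, and Ldha, lactate dehydrogenase, by 1.15 ± 0.10. Vegfa, a blood vessel growth factor, rose 2.83-fold (95% interval of the log2 change 1.03 to 1.97). The collagen prolyl hydroxylase P4ha1 rose by 1.21 ± 0.16 and the sodium channel gene Scn9a by 1.24 ± 0.10. The 3% O2 arrays were uneven, with Slc16a3 at 11.13, 9.24 and 10.03 in replicates 1, 2 and 3. Replicate 1 was also the highest of them for Pdk1, Ldha, Vegfa, P4ha1 and Bnip3, but not for Scn9a. The standard errors come from all 24 arrays and do not show this spread. Of 20 measured glycolysis and glucose uptake genes, 11 rose, 0 fell and 9 did not pass, and 15 rose when adjusted over the list alone. Camera called this list up (adjusted p = 3.1e-26), with adjusted p = 0.081 with an estimated correlation. Of 37 other textbook targets of the hypoxia-inducible factor HIF, 8 rose and 29 did not pass, and 13 rose and 1 fell when adjusted over the list alone (camera adjusted p = 2.5e-13, adjusted p = 0.24 with an estimated correlation). The p53 target Ccng1 fell by 0.61 on the log2 scale (SE 0.07). Its list had 2 of 16 members lower, 5 when adjusted over the list alone (camera adjusted p = 6.1e-05, adjusted p = 0.24 with an estimated correlation). Wfdc17 and Cd180, both known from macrophages, fell by 0.85 (SE 0.13) and 0.75 (SE 0.14), Cd180 by 0.48 without 3% O2 replicate 1, the lowest array for both genes. Of 17 microglia and macrophage markers 0 passed over all genes, while 7 were lower when adjusted over the list alone (camera adjusted p = 0.0025, adjusted p = 0.78 with an estimated correlation). Neither Nes nor Tubb3 passed, at -0.13 ± 0.16 and -0.34 ± 0.20. In all, 164 probe sets rose and 115 fell, and 157 rose and 160 fell after median centring. A fit of the 6 compared arrays alone called 4, namely Snord104, Clu, Gal and Npr2, named after their values were seen, and none of the hypoxia genes above. Quantile normalization gave 422, the brighter probe sets alone 156 and array weights 423, and the count was 149, 141 and 179 without 3% O2 replicate 1, 3% O2 replicate 2 and 21% O2 replicate 3.

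The same question in long-term midbrain cultures gave a much longer list, with 2614 probe sets higher and 2970 lower at 3% O2. Cd93, a cell surface glycoprotein known from endothelium, rose by 3.55 ± 0.32 (adjusted p = 1.2e-07), the collagen gene Col12a1 by 2.89 ± 0.26, Ier3, an early response gene, by 2.67 ± 0.16 and the phosphofructokinase Pfkp by 2.50 ± 0.21. Gjc3, a gap junction gene of oligodendrocytes, fell by 2.67 (SE 0.35), Gpr17, a receptor of oligodendrocyte precursors, by 2.18 (SE 0.42) and the cholesterol exporter Abca1 by 2.09 (SE 0.24). Of 17 oligodendrocyte lineage genes 1 rose, 2 fell and 14 did not pass, the same adjusted over the list alone, and Cspg4 of that list, also a pericyte marker, rose by 0.50 ± 0.10 while Olig2 did not pass (-0.06 ± 0.14). HIF targets had 25 members higher, 2 lower and 10 not passed of 37, and 28 higher and 2 lower when adjusted over the list alone (camera adjusted p = 2.2e-15, adjusted p = 0.16 with an estimated correlation). Adm, the vasodilator peptide adrenomedullin, rose by 2.11 ± 0.16, while Hif1a itself fell by 0.39 (SE 0.06). Glycolysis genes had 13 of 20 members higher, 15 adjusted over the list alone (camera adjusted p = 4.4e-08, adjusted p = 0.32 with an estimated correlation). Slc2a3, a glucose transporter, rose by 1.96 ± 0.23. Integrated stress and unfolded protein genes had 16 higher and 2 lower of 27, the same counts adjusted over the list alone (camera adjusted p = 2.7e-08, adjusted p = 0.12 with an estimated correlation). The amino acid transporter subunits Slc7a5 and Slc3a2 rose by 0.96 ± 0.08 and 0.71 ± 0.06. Of 16 p53 targets 11 rose and 1 fell, and 13 and 1 when adjusted over the list alone (camera adjusted p = 6.3e-07, adjusted p = 0.12 with an estimated correlation). Matrix genes had 15 higher and 1 lower of 26, the same counts adjusted over the list alone (camera adjusted p = 4.1e-05, adjusted p = 0.24 with an estimated correlation). The membrane protease Mmp14 rose by 1.59 ± 0.12. The list of pericyte, fibroblast and meninges markers moved with them, with 9 of 18 members higher, also 9 adjusted over the list alone, Postn by 2.33 ± 0.36 (camera adjusted p = 7.6e-05, adjusted p = 0.35 with an estimated correlation). Of 15 endothelial markers 3 rose, 0 fell and 12 did not pass, also 3 higher adjusted over the list alone, with a median of -0.02, a mean of 0.22 and a camera adjusted p of 0.34. Emcn rose by 1.17 ± 0.31, and Flt1 by 1.07 ± 0.30, a call lost without 3% O2 replicate 1 or 3 or 21% O2 replicate 1 (0.79, 0.79 and 0.94) and larger without 3% O2 replicate 2 (1.63). Of 37 cell cycle genes 14 rose, also 14 adjusted over the list alone (camera adjusted p = 3.2e-06, adjusted p = 0.59 with an estimated correlation). The Notch modifier Mfng fell by 1.32 (SE 0.10) and the Notch ligand Dll1 by 1.11 (SE 0.11). Array weights raised the count of 5584 changed probe sets to 9832, and to 9494 with a second weight estimator.

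In the cortex arrays labelled 48 h, 1462 probe sets were higher and 1424 lower at 3% O2. The amino acid transporter gene Slc7a3, which carries arginine and lysine, rose by 2.34 ± 0.25, Slc7a11, the cystine importer, by 2.27 ± 0.17 (adjusted p = 8.4e-08) and Slc38a4 by 2.25 ± 0.27. The Notch effector Hey2 fell by 1.65 (SE 0.28), Abca1 by 1.72 (SE 0.24) and Id4, an inhibitor of differentiation factors, by 1.44 (SE 0.29). Integrated stress genes had 15 of 27 members higher and 0 lower, and 15 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.2e-12, adjusted p = 0.046 with an estimated correlation). Of 37 HIF targets 17 rose and 0 fell, 21 adjusted over the list alone (camera adjusted p = 3.5e-10, adjusted p = 0.19 with an estimated correlation). The oxidoreductase Ero1a rose by 1.30 ± 0.16 and Adm by 1.15 ± 0.16. Glycolysis genes had 5 of 20 higher, 14 adjusted over the list alone (camera adjusted p = 5.4e-06, adjusted p = 0.35 with an estimated correlation). Slc2a1 and Vegfa did not pass, at 0.55 ± 0.20 and 0.55 ± 0.23. Arrays at 21% O2 were uneven for these lists. Glycolysis genes had a mean of 10.98 ± 0.31 (log2, SD, n = 3) there against 11.40 ± 0.12 at 3% O2. HIF targets had 9.35 ± 0.25 against 9.84 ± 0.20. The standard errors come from all 24 arrays and do not show this spread. Of 17 NRF2 targets, which answer oxidative stress, 8 rose, 10 adjusted over the list alone (camera adjusted p = 1.3e-07, adjusted p = 0.078 with an estimated correlation). Neuron genes had 11 members lower and 1 higher of 24, 14 and 1 adjusted over the list alone (camera adjusted p = 6.3e-07, adjusted p = 0.078 with an estimated correlation). The synaptic vesicle gene Syt1 fell by 0.92 (SE 0.09) and Neurod1 by 0.95 (SE 0.12). Notch targets and ligands had 8 lower and 2 higher of 16, 10 and 2 adjusted over the list alone (camera adjusted p = 8.1e-05, adjusted p = 0.078 with an estimated correlation). The glycosyltransferase Mfng fell by 1.15 (SE 0.10). Replicate 1 at 21% O2 stood apart from its group (r = 0.986 with replicate 2), and leaving out both number 1 arrays, a setting chosen after the data were seen, gave 3460 changed probe sets. The count of 2886 was 1725 without 21% O2 replicate 3, 311 in a fit of the 6 arrays alone, and 8876 or 6299 with array weights by either of the estimators.

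In the cortex arrays labelled 13 d the response was short and mostly upward, with 127 probe sets higher and 15 lower. Slc16a3 rose by 4.32 ± 0.30 (adjusted p = 2.3e-07), Bnip3, a mitophagy receptor, by 3.08 ± 0.30, Pdk1 by 2.74 ± 0.23, Egln3, a HIF prolyl hydroxylase, by 2.44 ± 0.21 and the glucose transporter Slc2a1 by 1.95 ± 0.20. The circadian repressor Ciart rose by 2.59 ± 0.24, and by 2.15 at another probe set. Glycolysis genes had 15 of 20 members higher and 0 lower, 17 adjusted over the list alone, and Ldha rose by 0.98 ± 0.10 (camera adjusted p = 7.8e-62, adjusted p = 0.00085 with an estimated correlation). Of 37 HIF targets 17 rose and 0 fell, 27 adjusted over the list alone, P4ha1 by 1.56 ± 0.16 (camera adjusted p = 2.4e-63, adjusted p = 0.00085 with an estimated correlation). Cholesterol synthesis genes had 1 of 18 higher over all genes and 13 adjusted over the list alone (camera adjusted p = 1.1e-19, adjusted p = 0.094 with an estimated correlation). Ccng1 fell by 0.42 (SE 0.07), the p53 target list having 1 of 16 lower and 3 adjusted over the list alone (camera adjusted p = 1.4e-05, adjusted p = 0.11 with an estimated correlation). Neuron genes had 0 of 24 past the threshold, also 0 adjusted over the list alone, with a median change of 0.03. Nes, Sox2 and Mki67 did not pass, at -0.25 ± 0.16, -0.02 ± 0.07 and -0.03 ± 0.10. The count of 142 was 93, 68 and 82 without 3% O2 replicates 1, 2 and 3, and 91 and 75 without 21% O2 replicates 2 and 3. It was 348 in a fit of the 6 arrays alone, with 78.7% of calls higher against 89.4%, and 920 (55.4% higher) or 815 with array weights by either of the estimators.

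**Figure D2:**
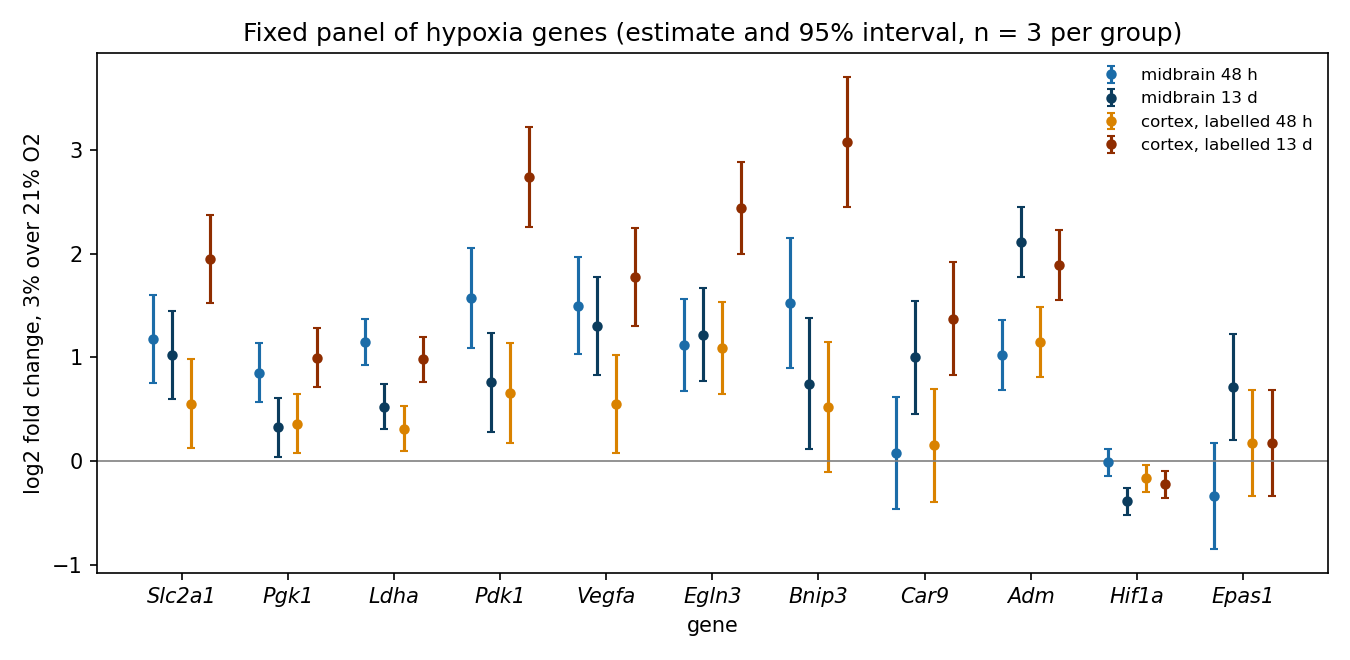
Log2 fold change of 3% over 21% O2 (y axis) for 11 hypoxia genes of the fixed panel (x axis) in the 4 region and time groups, with 95% intervals from limma and n = 3 arrays per group. Bnip3 spans 0.52 in cortex labelled 48 h to 3.08 in cortex labelled 13 d, and Hif1a lies at or below 0 in each comparison.

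The 4 oxygen comparisons share no arrays, though they share 1 error estimate. In all 4 of them 14 probe sets of 13 genes were higher and 0 were lower. The 13 genes, listed without regard to the naming rule, were Slc16a3, Adm, Egln3, Pfkp, Ciart, Ache, Kdelr3, P4ha1, Fam162a, A2m, Pkm, Rlf and Plpp5. Midbrain 13 d and cortex labelled 48 h shared 856 higher probe sets, where independent lists of these sizes would share 163, and 827 lower ones against 181. Their fold changes correlated at r = 0.61 across probe sets, which are not independent replicates. Midbrain 48 h and cortex labelled 13 d shared 42 higher probe sets against 0.89 for independent lists (r = 0.38). Across the other 4 pairs r lay between 0.10 and 0.18. These pairs also shared more higher probe sets than independent lists would. The numbers were 49 against 7.93 for the cortex groups and 71 against 14.2 for the 13 d groups. They were 42 against 18.3 for the midbrain groups and 32 against 10.2 for the 48 h groups, times as labelled.

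Whether oxygen acted differently at 13 d and at 48 h was tested as a difference of responses. In midbrain 3536 probe sets differed, 1606 with a more positive response at 13 d and 1930 with a more negative one. Cd93 differed by 2.81 ± 0.45, Col12a1 by 2.53 ± 0.37 and Lrrc32, a carrier of latent TGF-beta, by 2.46 ± 0.15 (adjusted p = 8.7e-09). The response of Gjc3 was more negative at 13 d (-2.56 ± 0.50). Of 16 p53 targets 12 responded more positively and 1 more negatively, the same counts adjusted over the list alone (camera adjusted p = 4.7e-09, adjusted p = 0.064 with an estimated correlation). The response of Ldha was smaller at 13 d (-0.62 ± 0.15), and that of Vegfa did not differ past the threshold (-0.20 ± 0.32). These times lie in different array runs, so only a run effect that adds equally to both oxygen levels cancels. The count was 6111 or 5708 with array weights.

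In cortex, 967 probe sets differed between the labelled times, 446 more positive at labelled 13 d and 521 more negative. Slc16a3 differed by 3.23 ± 0.42, Bnip3 by 2.56 ± 0.42, Pdk1 by 2.08 ± 0.32 and Txnip, an inhibitor of thioredoxin and of glucose uptake, by 1.95 ± 0.34. Glycolysis genes were uneven between the 21% O2 arrays labelled 48 h (SD of the list mean 0.31), which these standard errors do not show. The responses of Slc7a11 (-2.64 ± 0.23) and Slc7a3 (-2.09 ± 0.35) were more negative at labelled 13 d, where neither gene passed (-0.37 ± 0.17 and 0.24 ± 0.25). Glycolysis genes had 8 of 20 members more positive, 13 adjusted over the list alone (camera adjusted p = 2.2e-12, adjusted p = 0.13 with an estimated correlation). Integrated stress genes had 9 of 27 more negative, 11 adjusted over the list alone (camera adjusted p = 9.5e-11, adjusted p = 0.092 with an estimated correlation). The count was 2970 without 48 h 21% O2 replicate 1, 538 and 429 without replicates 2 and 3 of that group, 542 and 524 without 13 d 3% O2 replicates 1 and 2, and 567 and 600 without 13 d 21% O2 replicates 2 and 3. It was 377 in a fit of the 12 arrays alone and 5635 or 4323 with array weights.

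Between the regions at labelled 48 h, 1377 probe sets responded differently, 677 more positively in midbrain and 700 more negatively. Slc7a11 (-2.44 ± 0.23), the chloride channel gene Clic5 (-2.08 ± 0.32) and Slc38a4 (-1.95 ± 0.38) responded lower in midbrain, and the phosphodiesterase Pde9a (1.68 ± 0.30), the adenylate cyclase Adcy8 (1.67 ± 0.17) and Ldha (0.83 ± 0.15) higher. Integrated stress genes had 12 of 27 more negative in midbrain, 13 adjusted over the list alone (camera adjusted p = 4e-08, adjusted p = 0.14 with an estimated correlation). Against the cortex arrays labelled 13 d, a comparison chosen after the data were seen, the midbrain 48 h response differed in 5 probe sets, those of Scn9a, Gal and Tas2r108 (more positive in midbrain) and of Ndufa4l2 and Kbtbd11 (more negative), named after their values were seen. The count was 3084 without cortex 21% O2 replicate 1, 752 without its replicate 3, 331 in a fit of the 12 arrays alone, 2116 with the replicate block and 5112 or 3597 with array weights.

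Between the regions at labelled 13 d, 3162 probe sets responded differently, 1570 more positively in midbrain and 1592 more negatively. Cd93 (2.94 ± 0.45), Angpt2, a vessel destabilising factor (2.55 ± 0.51), and Postn (2.39 ± 0.51) responded higher in midbrain, and Slc16a3 (-2.94 ± 0.42), Txnip (-2.39 ± 0.34) and Bnip3 (-2.33 ± 0.42) lower. Of 16 p53 targets 11 responded more positively in midbrain and 1 more negatively, 12 and 1 adjusted over the list alone (camera adjusted p = 3.7e-09, adjusted p = 0.062 with an estimated correlation). Against the cortex arrays labelled 48 h, again chosen after the data were seen, the midbrain 13 d response differed in 1540 probe sets. These groups lie in different array runs, and the count was 4873 in a fit of the 12 arrays alone and 6993 or 6745 with array weights.

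The regions were also compared at 21% O2 and labelled 48 h, where 5690 probe sets were higher in midbrain and 7138 lower. Because the cortex arrays labelled 48 h resembled midbrain 13 d, region and culture time may be mixed in this comparison. The transcription factor genes Tfap2b (5.78 ± 0.05) and Tfap2d (4.81 ± 0.09), the glutamate transporter gene Slc17a6 (4.68 ± 0.10) and the macrophage lysozyme gene Lyz2 (5.29 ± 0.30) were higher in midbrain. The metallothionein gene Mt2 (-4.00 ± 0.20), Egln3 (-3.55 ± 0.21) and Slc16a3 (-3.36 ± 0.30) were lower. Of 25 midbrain and dopaminergic genes 21 were higher, also 21 adjusted over the list alone, with Gata3 at 4.57 ± 0.11, En1 at 1.43 ± 0.23 and Th, the dopamine synthesis enzyme, at 0.78 ± 0.11 (camera adjusted p = 2.9e-08, adjusted p = 0.043 with an estimated correlation). All 24 neuron genes were higher in midbrain, all 24 adjusted over the list alone (camera adjusted p = 1.4e-16, adjusted p = 0.0079 with an estimated correlation), with Tubb3 at 3.66 ± 0.20. All 37 cell cycle genes were lower, 37 adjusted over the list alone (camera adjusted p = 6.5e-16, adjusted p = 0.32 with an estimated correlation). Of 17 microglia and macrophage markers 16 were higher in midbrain, 16 adjusted over the list alone (camera adjusted p = 1.4e-09, adjusted p = 0.21 with an estimated correlation), and of 17 oligodendrocyte lineage genes 14 were lower, 14 adjusted over the list alone (camera adjusted p = 2.7e-05, adjusted p = 0.41 with an estimated correlation). Of 16 Notch targets and ligands 13 were lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 2.7e-05, adjusted p = 0.043 with an estimated correlation). Cortical identity genes split, with 6 higher and 6 lower of 20, the same adjusted over the list alone.

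Cortex arrays labelled 13 d were compared with those labelled 48 h at 21% O2, within 1 array run, and 3929 probe sets were higher and 4771 lower at labelled 13 d. The cortical neuron genes Tbr1 (4.57 ± 0.10) and Neurod6 (4.43 ± 0.20) and the axon growth gene Stmn2 (3.53 ± 0.18) were higher. Gjc3 (-4.22 ± 0.35), Gpr17 (-3.60 ± 0.42) and Slc16a3 (-3.39 ± 0.30) were lower. Of 24 neuron genes 23 were higher, also 23 adjusted over the list alone (camera adjusted p = 2e-26, adjusted p = 0.0007 with an estimated correlation). GABAergic and ventral forebrain genes had 14 higher and 1 lower of 16, 15 and 1 adjusted over the list alone, with Gad2, the GABA synthesis enzyme, at 3.16 ± 0.11 and Dlx5 at 3.04 ± 0.11 (camera adjusted p = 2.8e-16, adjusted p = 0.0058 with an estimated correlation). Cortical identity genes had 13 higher and 1 lower of 20, 14 and 1 adjusted over the list alone (camera adjusted p = 2.6e-08, adjusted p = 0.0048 with an estimated correlation). Of 17 oligodendrocyte lineage genes 15 were lower, 15 adjusted over the list alone (camera adjusted p = 2.6e-08, adjusted p = 0.19 with an estimated correlation). Of 37 HIF targets 25 were lower and 3 higher, the same adjusted over the list alone, with Adm at -2.53 ± 0.16 and Bnip3 at -2.94 ± 0.30 (camera adjusted p = 1.2e-07, adjusted p = 0.31 with an estimated correlation). Nes did not pass, at -0.38 ± 0.16. The count of 8700 was 14033 with array weights.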

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

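The differences of responses are listed because the test of the difference itself called many probe sets. The tests of explanations were chosen after the result was seen, except the freely drawn splits of the samples and the test on genes that rose in midbrain 48 h. The oxygen response differed between 13 d and 48 h in 3536 probe sets in midbrain and 967 in cortex, and between midbrain and cortex in 1377 at labelled 48 h and 3162 at labelled 13 d.

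Among 100 drawn relabellings of oxygen within the groups, real one included, 3 gave as many probe sets for midbrain (highest other 4217), 2 for the regions at 48 h (1909), 4 for the regions at 13 d (3735) and 8 for cortex (1712). These draws break the pairs of same-numbered midbrain arrays. Among all relabellings that part each midbrain pair as the real one does, 2 of 32 gave as many for midbrain, 2 of 80 for the regions at 48 h and 5 of 80 for the regions at 13 d. By these shares alone, chance was not excluded for midbrain, the regions at 13 d or cortex. For the regions at 48 h the share lay under 0.05 in both sets of relabellings, 1 of 4 such tests, which were not adjusted for their number. Relabelling also breaks the oxygen response of both compared groups, so it cannot tell whether 2 real responses are equal. In each case the highest count came from exchanging all oxygen labels in 1 of the compared groups, which turns a difference of responses into their sum. Without that exchange the highest other counts among the relabellings that keep the pairs parted were 3470 for midbrain, 1196 for the regions at 48 h and 3580 for the regions at 13 d. The real counts were 3536, 1377 and 3162. For midbrain and the regions at 48 h only the exchange matched the real count in this set. Because the exchange gives a sum of responses, the midbrain share of 2 of 32 does not decide on chance. The comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave the most in each. Of these, 4 splits part the midbrain pairs as the real one does, with a highest other count of 1 at 48 h and 0 at 13 d. The real and highest other counts over the 10 splits were 279 and 16 in midbrain 48 h, 5584 and 0 in midbrain 13 d, 142 and 4 in cortex 13 d, 12828 and 1 between regions and 8700 and 2 between cortex times. In cortex 48 h they were 2886 and 1841, the latter from exchanging 3% O2 replicate 2 with 21% O2 replicate 1, the array that stands apart.

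The cortex arrays labelled 48 h resemble midbrain 13 d, and those labelled 13 d resemble midbrain 48 h, in correlation across probe sets and in neuron and oligodendrocyte genes. Cell cycle genes differed from this. At 21% O2 their mean in cortex labelled 13 d (10.29) lay nearer to midbrain 13 d (10.08) than to midbrain 48 h (9.00). Array run is argued against, since cortex labelled 48 h, in run 2, correlated at 0.982 or more with midbrain 13 d in run 1 but at 0.970 or less with other groups of its own run. An exchange of the culture time labels between the cortex arrays is a candidate explanation. The 13 d minus 48 h differences at 21% O2 correlated at r = -0.82 across probe sets between the regions, which largely restates the resemblance. With cortex times crossed the response differed in 5 probe sets in place of 1377 and in 1540 in place of 3162. The crossing also pairs responses of similar size, with 279 and 142 changed probe sets in the groups behind the 5. A real difference between the regions could give the same values, so they do not favour an exchange. A real difference between regions in how the cultures change with time stays open, with 23 of 24 neuron genes higher at labelled 13 d in cortex against a median of -3.62 in midbrain, because no value used here records the culture time. If the labels were exchanged, both cortex oxygen comparisons would keep their values and trade names, both cortex time comparisons would change sign, and the region comparisons would mix region and time.

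More probe sets changed at 3% O2 in midbrain 13 d and cortex 48 h than in the other 2 groups, while median sizes of the log2 changes, a first test that decided nothing and was replaced, were 0.0926 and 0.0801 against 0.0736 and 0.0520. A shared error estimate too small for those arrays is argued against for midbrain 13 d, where a fit of its own 6 arrays called 6700, against at most 348 in midbrain 48 h and cortex 13 d. For cortex 48 h such a fit called 311, fewer than those 348, so the larger count there rests on the error shared by all arrays and this explanation stays open, although its fold changes followed those of midbrain 13 d (r = 0.61). More fibroblast and pericyte RNA at 3% O2 cannot be told apart from a response of the cells, with a list median of 0.52 in midbrain 13 d and of 0.10 in cortex 48 h, since no value gives the share of such cells; in cortex 48 h the bound first written, a share of the midbrain median, counted against it, and was dropped after the result was seen because the members had an interquartile range of 0.35. Culture time and region stay open as biological explanations, untested.

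HIF targets lay higher at 21% O2 in midbrain 13 d and cortex 48 h than in the other 2 groups. Array run is argued against for the cortex arrays, since within run 2 the list median differed by 0.70 between the cortex times, with an interquartile range of 1.22. In midbrain the times lie in different runs, so run stays open there. Less oxygen reaching the cells at 21% O2 stays open: the 164 probe sets that rose in midbrain 48 h had a median difference of -0.01 between the cortex times, at percentile 5.7 of 10000 random lists matched on level. The bound written before that test counted this against the explanation, and 48.8% of the members were higher in cortex 48 h. A wider bound was set after the result was seen, because the members' interquartile range of 0.67 exceeds their median rise of 0.44 in midbrain 48 h. That range is a spread of members and not the uncertainty of their median, so the explanation stays open only by the later bound. Fewer neurons cannot be told apart, with progenitor genes at 0.38 against 0.70 for HIF targets and an interquartile range of 1.22.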

How the results depend on the processing

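The fits of the 12 midbrain arrays, the crossed cortex times, the gene-by-gene weights and the omission of both number 1 arrays were chosen after the data were seen; the other settings were planned. No named gene that passed in the main fit reversed under quantile normalization, centring, the variance trend, the block or leaving out 1 array. No called list reversed under an estimated correlation, fry, quantile normalization or the block. The signs of named genes that did not pass were not compared. Named genes were not refitted under the other settings, and of the 12828 called probe sets between regions, 4 reversed sign with array weights and 7 after quantile normalization. Counts changed as follows, and the cause of these changes was not tested. In midbrain 48 h (279) the brighter probe sets gave 156, quantile normalization 422, the 6 arrays alone 4 and array weights 423, and leaving out 1 array 141 to 302, and all 4 calls of the 6 arrays were higher. In midbrain 13 d (5584) array weights gave 9832 and gene-by-gene weights 9494, and leaving out 1 array 4418 to 5400. In cortex 48 h (2886) the 6 arrays alone gave 311, weights 8876 and 6299, and leaving out 1 array 1725 to 4210. In cortex 13 d (142) the 6 arrays alone gave 348, weights 920 and 815, and leaving out 1 array 68 to 110. The time difference in midbrain (3536) became 6111 and 5708 with weights and 2738 to 3531 with 1 array left out, and that in cortex (967) 5635 and 4323 with weights, 377 with the 12 arrays alone, 1596 with the replicate block and 429 to 2970 with 1 array left out. The region difference at 48 h (1377) became 5112 and 3597 with weights, 331 with the 12 arrays alone, 2116 with the replicate block, 5 with crossed cortex times and 752 to 3084 with 1 array left out. That at 13 d (3162) became 6993 and 6745 with weights, 4873 with the 12 arrays alone, 1540 with crossed times and 2339 to 3260 with 1 array left out. The cortex time comparison (8700) became 14033 with weights and 7536 to 8675 with 1 array left out, and that between regions (12828) 11915 to 12860. The fit of 12 midbrain arrays gave 213 at 48 h and 5914 at 13 d, and omitting both number 1 arrays 3460 in cortex 48 h. The default weight estimate did not converge and gave 1 array, cortex 48 h 21% O2 replicate 3, a weight of 38.9 (5.05 with the gene-by-gene estimator). With the default weights the mean of that group leans on that array, and how far the counts do was not tested. The replicate block gave 368 in midbrain 48 h, 6052 in midbrain 13 d, 3507 in cortex 48 h, 170 in cortex 13 d, 4137 for the midbrain time difference, 3712 for the regions at 13 d, 10649 between regions and 6295 between cortex times. Same-numbered arrays correlated at 0.29, 0.42 and -0.04 in cortex 48 h and at -0.01, 0.23 and -0.37 in cortex 13 d, so the block is only a setting there. Among named genes the block ended 22 calls and added 30, quantile normalization ended 5 and added 14, and leaving out 1 array ended 418 and added 73 over all omissions. Of list calls, 99 were lost with an estimated correlation, 29 with fry, 6 after quantile normalization and 3 with the block. Arrays of a group number 3, and signal over background is not known.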

Other observations

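Of 18 cholesterol synthesis genes 10 rose, 0 fell and 8 did not pass at 3% O2 in midbrain 13 d, and 12 rose when adjusted over the list alone (camera adjusted p = 2.5e-06, adjusted p = 0.39 with an estimated correlation). The reductase gene Hsd17b7 rose by 0.88 ± 0.11 (log2, SE, n = 3 per group) and the epoxidase gene Sqle by 0.66 ± 0.08. NRF2 targets had 8 higher and 1 lower of 17, 9 and 1 adjusted over the list alone, and Gclc, an enzyme of glutathione synthesis, rose by 1.16 ± 0.11 (camera adjusted p = 4.7e-05, adjusted p = 0.24 with an estimated correlation).

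At 21% O2 the mean of 17 microglia and macrophage markers was 8.25 ± 0.07 (log2, SD, n = 3) in midbrain 48 h, 6.81 ± 0.03 in cortex labelled 13 d, 6.41 ± 0.03 in midbrain 13 d and 6.41 ± 0.04 in cortex labelled 48 h. The same 17 genes had a mean of 8.03 ± 0.32 in midbrain 48 h at 3% O2. The neuropeptide gene Npy was higher at 3% O2 in midbrain 48 h (0.48 ± 0.11) and in cortex labelled 13 d (0.51 ± 0.11), the groups with high neuron levels, though both calls were lost with the replicate block and on leaving out single arrays.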
